A study of Mus musculus with 2 samples.

How the data were processed

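Messenger RNA of mouse liver was profiled in 2 libraries, 1 from WT and 1 from Gbp5 KO mice, each a pool of RNA from 4 livers per the labels' design text, sequenced on an Illumina instrument. The labels call the wild type and the knockout by genotype, and groups were taken from those labels alone. Per the submitters' processing notes, TopHat2, HTSeq 0.6.1 and the genome build GRCm38 were used; the annotation release, strand setting and filters are not given in the sources used here. The deposited files call their values FPKM, but they hold whole-number read counts per gene, with 2707 genes at exactly 1 read in WT and different totals per library, so the values deposited by the authors were read as raw counts with no normalization. The design written before the data were examined assumed FPKM. FPKM was therefore computed here from the counts, with the reads assigned to genes as the library total and the union of a gene's exons in GENCODE M21 (GRCm38) as its length. The annotation may differ from the one used for counting, which would change lengths and so FPKM levels, but not the ratio of a gene's CPM between libraries. Log2 differences on FPKM with 1 added and the filter at 1 FPKM do depend on length. The 2-fold calls, list medians and percentiles drawn from them could therefore change.

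Each table listed 52845 entries, of which 52636 were Ensembl genes and 209 carried a label with no annotated gene. The latter held 0.652% of counts in WT and 0.496% in KO and were left out of library totals and of all comparisons. Of the Ensembl genes, 52403 were found in the annotation, and 233 were not; those kept their reads in the totals, 0.0515% in WT and 0.0232% in KO, and were not compared. Totals over genes were 19864848 and 15750875, so a count of 0 allows up to 3 reads, or 0.151 and 0.190 CPM. The WT library was 1.26 times as deep, and its low counts are the more precise ones.

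With 1 library per group no test across replicates exists. The difference was log2((KO + 1)/(WT + 1)) on FPKM among genes at 1 FPKM or more in either library, and genes were counted as different at 2-fold by that rule of size. This scale understates differences of low genes. Ratios of KO to WT in the text are ratios of CPM without a pseudocount, with exact 95% Clopper-Pearson intervals conditional on the sum of the reads of both libraries. They compare these libraries, not the genotypes, and reads are not independent molecules. For each of 44 gene lists fixed before the data were examined, the median was placed among 10000 random lists of equal size matched on mean expression in 20 bins, as a description of these libraries. A list stood apart below percentile 2.5 or above 97.5, and lists with under 5 measured members got none. The lists held 767 genes, and 3 symbols were not found.

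Genes named in the text followed a rule fixed at the same time: Gbp5 and its family, the 14 highest and 14 lowest genes at 5 FPKM or more with predicted and clone-named genes left out, the 2 highest and 2 lowest members of each described list, and set representatives such as Tnf, Alb and Clec4f. Genes outside it, among them Epcam, mt-Co1, mt-Co2, mt-Atp8 and Xist, were chosen after their values were seen. The tissue lists of the closing section were written after the genes highest in KO had been seen; the 9 genes named there as a set were picked from those highest genes after their values were seen, and the simple epithelium and intestinal lists before the values of their own members were looked at. A single gene that the rule names is not reported here.

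Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, median ratio scaling, an equal FPKM sum (TPM) with and without the 50 most abundant genes, no filter, and a filter at 5 FPKM. Alternatives chosen after seeing the data were a correction for GC content and length, CPM in place of FPKM, TMM scaling, protein-coding genes only, and totals without mitochondrial genes. The correction took the median log2 difference of genes with 100 reads or more in 10 GC bins by 4 length bins from each gene. It also removes any real difference that goes with GC content or length. Nuclear copies of mitochondrial genes were found with blastn 2.17.0. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and edgeR 4.0.16 in R 4.3.3 for TMM factors alone.

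The steps were tested on simulated Poisson counts of the KO against WT comparison with 50 genes changed each way per fold size. The counts held no variation between animals, pools or library preparations. The shares of unchanged genes called below thus cover counting error only and are not a rate of false calls for single pools. Over 11405 genes without a trend, 100% of 4-fold changes were found, as were 100% of 2.83-fold increases and 96% of 2.83-fold decreases, and 1.05% of unchanged genes were called. With a trend in GC content alone added, over 11671 genes, 76% and 86% of 2.83-fold changes were found and 1.94% of unchanged genes called. The correction, over 11483 genes, raised these to 98% and 94% and lowered the last to 1.13%. The placing of lists was checked on the real log2 differences instead. Of 100 lists of 15 genes drawn at random with no shift added, 3% fell outside the limits, and 90% fell below when shifted by -0.5. Genes of a fixed list may vary together, unlike genes drawn at random, so the 3% may not hold for the fixed lists.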

Results

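Liver RNA from wild-type (WT) mice and from mice lacking Gbp5 was compared 6 h after injection of D-galactosamine with lipopolysaccharide. Lipopolysaccharide is a bacterial endotoxin, and D-galactosamine depletes uridine nucleotides in hepatocytes and makes the liver sensitive to it. Gbp5 encodes guanylate-binding protein 5, an interferon-inducible GTPase. The mice were C57BL/6, 9 weeks old, and received 800 µg D-galactosamine and 100 ng lipopolysaccharide per g body weight. RNA of 4 livers was pooled for each genotype and sequenced as 1 library, so the 2 libraries hold no replicates. Differences between them have no replicate check and no p-value, and intervals below are 95% counting intervals that cover counting error only. No untreated library was analysed here, so all comparisons are between genotypes under treatment. The WT library held 19864848 reads assigned to genes and the knockout (KO) library 15750875. A floor of 3 reads corresponded to 0.151 CPM, reads scaled to library size in WT and 0.190 in KO. At least 1 read was found for 22485 genes in WT and 23066 in KO. The most abundant transcript was Apoe in WT, with 4.59% of reads, and Alb in KO, with 6.92%.

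The first question was whether the targeted gene differed between the libraries. Gbp5 (ENSMUSG00000105504, GRCm38 chromosome 3, 142493978 to 142522344, plus strand) had 3211 reads in WT and 873 in KO, or 24.4 and 8.35 FPKM, a read density scaled to gene length and library size. It was 2.92-fold lower in KO (interval 2.71 to 3.15), a log2 difference of -1.44. The genotype labels and this difference point the same way, and reads of Gbp5 remained in KO at 34.3% of the WT level (31.8% to 37.0%). The counts are per gene and do not show which exons those reads cover. All 10 guanylate-binding protein genes measured at 1 FPKM or more were lower in KO. Gbp10 was lower by a log2 difference of -0.91 and Gbp8 by -0.86, whereas Gbp9 differed by -0.25 and Gbp6 by -0.27. Gbp2, the most abundant member, had 92.6 FPKM in WT and 68.6 in KO, and Gbp2b lay under 1 FPKM in both, with 21 and 4 reads. On the size rule Gbp5 alone passed a 2-fold difference, joined by Gbp10 at -1.02 after a correction for GC content and length. That rule adds 1 to each FPKM and so shrinks differences of low genes. As ratios of CPM, Gbp10 was 2.56-fold lower (1.98 to 3.35), Gbp8 2.45-fold (1.86 to 3.26) and Gbp2b 4.16-fold (1.40 to 16.7). Their intervals overlap that of Gbp5, so the rule does not set Gbp5 apart from them, whereas Gbp9 was 1.20-fold lower. The median of the list was -0.50, at percentile 2.23 of 10000 expression-matched random lists. That list includes the targeted gene Gbp5 itself, and no percentile without it is given here. The percentile was 2.65 with median ratio scaling and 10.2 among genes at 5 FPKM or more, both inside the range of random lists, and 0.02 with a median of -0.66 after the correction. Gbp4, Gbp8 and Gbp9 overlap one another in the annotation and the family is similar in sequence, so the split of reads between members is uncertain.

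**Figure D1:**
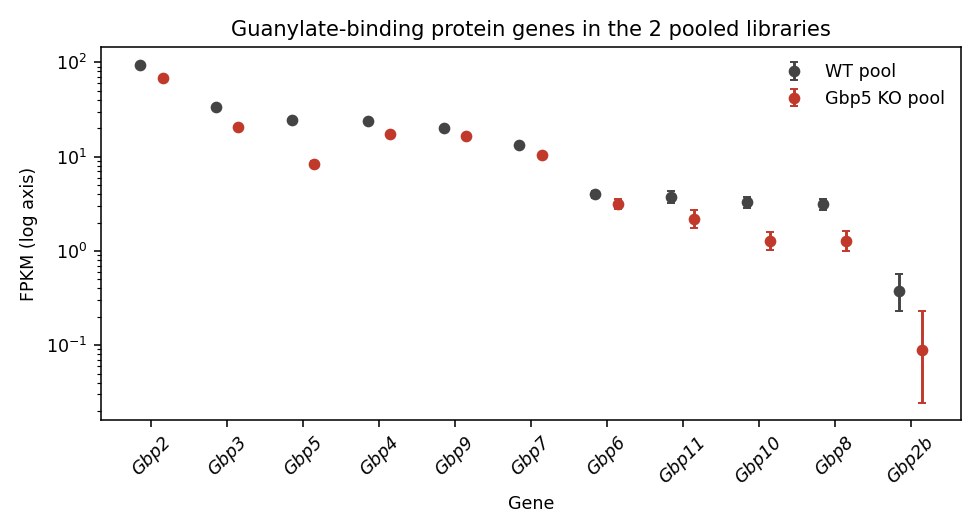
FPKM (log axis) of the 11 guanylate-binding protein genes in the WT pool (grey) and the Gbp5 KO pool (red), with 1 library per group and bars for 95% Poisson counting intervals. Every gene lies lower in KO, and Gbp5 goes from 24.4 to 8.35.

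The 14 genes highest in KO relative to WT included Dmbt1, Ctrb1 and Ly6d. Dmbt1, a secreted mucosal scavenger receptor, had 20 reads in WT and 4319 in KO, 272-fold higher (interval 176 to 446). Ctrb1, a chymotrypsinogen, had 0 and 297 reads and was at least 125-fold higher against a floor of 3 reads. Ly6d was 22.6-fold higher (14.9 to 36.1), and the trefoil peptide gene Tff2 was 19.5-fold higher (7.26 to 74.0) on 4 and 62 reads. Spink4 had 1 and 98 reads, a ratio of 124 (21.7 to 4931), and the calcium-binding protein gene S100g had 1 and 43 reads, a ratio of 54.2 (9.23 to 2191). The mucin gene Muc1 was 5.57-fold higher, Cd24a 4.37-fold and the ductal keratin gene Krt19 4.24-fold. Pnpla3, which encodes a lipid droplet protein of hepatocytes, was 9.26-fold higher (6.81 to 12.8). Mup15, Ndufb4c, Traj14 and Trbd1 completed the 14 highest, but Mup15 has near-identical relatives and Ndufb4c is a processed pseudogene, so their reads are uncertain, and Traj14 and Trbd1 rest on 3 reads and 1 read in KO.

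Among the 14 lowest genes, Moxd1, a monooxygenase gene, had 737 reads in WT and 1 in KO, a ratio of 584 (105 to 23112). The activin subunit gene Inhbb was 6.72-fold lower (6.32 to 7.16), Csf2ra, a receptor subunit for granulocyte-macrophage colony-stimulating factor, 5.92-fold, and Cfd, the complement protease factor D, 8.29-fold. Basp1 was 7.82-fold lower and Ccdc88b 10.9-fold lower. The GC and length correction moved Inhbb from -2.68 to -1.61, Csf2ra from -2.46 to -1.60 and Ccdc88b from -2.54 to -1.69. Pitx3 was 12.9-fold lower, but its annotation overlaps the end of the more abundant Elovl3, which itself had a log2 difference of -1.13, so its reads are uncertain. The remaining 7 were 4 mitochondrial genes and Mup13, Mup16 and Mup19. The major urinary protein genes are near-identical and their separate values are uncertain. Mup15 went from 11 to 15456 reads and Mup16 from 4388 to 75, while the 22 genes of the family together held 21710 CPM in WT and 23842 in KO, a ratio of 1.10.

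In all, 11821 genes reached 1 FPKM in either library. By a rule of size alone, 289 were at least 2-fold higher in KO and 785 at least 2-fold lower, so 73.1% of these genes were lower. The difference between libraries went with GC content. Over 10690 protein-coding genes, Spearman's rho between log2 difference and GC content was -0.49, a correlation across genes, which are not independent replicates. The median log2 difference went from 0.28 in the tenth of genes lowest in GC to -0.88 in the tenth highest. After a correction for GC content and length, chosen after seeing the data, 302 genes were higher and 368 lower, and the lower share was 54.9%. Of the original calls, 217 higher and 317 lower ones were kept. The lower share was 80.1% on CPM, 88.4% among genes at 5 FPKM or more and 88.5% with protein-coding genes only. No scaling moved the median of all genes by over 0.1.

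**Figure D2:**
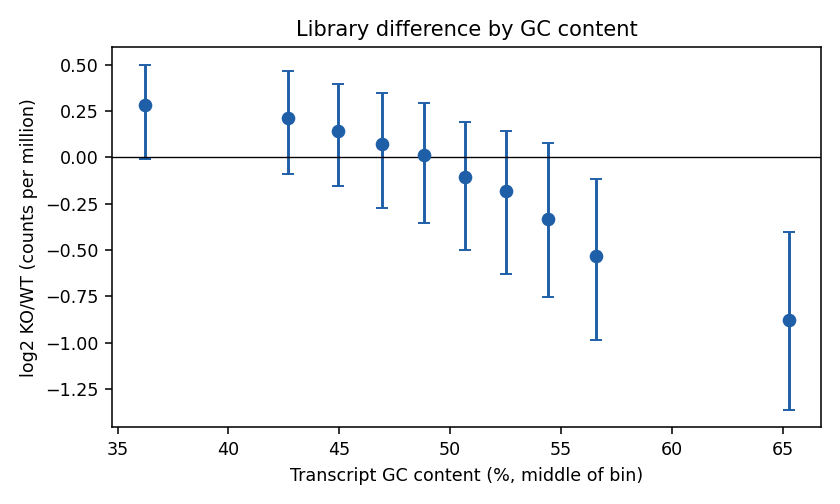
Log2 difference between the KO and WT pools (CPM) against the GC content (%) of the longest transcript, for 10690 protein-coding genes in 10 bins, with points for medians and bars from the lower to the upper quartile. The medians go from 0.28 to -0.88.

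Genes of the inflammatory response to endotoxin were lower in KO as groups. Of 15 measured inflammatory cytokine genes 14 were below 0, with a median of -0.81 that lay at percentile 0.01. Csf3, a neutrophil growth factor, was 3.32-fold lower (2.83 to 3.91), Il27 7.88-fold (4.78 to 13.9) and Il6 2.41-fold (1.93 to 3.03). Il1b was 1.64-fold lower (1.53 to 1.75) and Tnf 1.31-fold lower, while Tnfsf10 had a log2 difference of 0.05. Of 22 chemokine genes 18 were below 0, with a median of -0.46 at percentile 0.12. Ccl2, a monocyte attractant, was 1.37-fold lower (1.32 to 1.42), Cxcl9 1.23-fold and Cxcl10 1.20-fold. Ccl8 had 18 and 2 reads, a ratio of 7.14 (1.71 to 63.4). In the other direction, the neutrophil attractant Cxcl1 was 1.38-fold higher (1.31 to 1.44), and Ccl20 had 2 and 26 reads, a ratio of 16.4 (4.10 to 143). Its log2 difference of 1.01 became 0.84 after the GC and length correction. For NF-kB feedback and adhesion genes the median was -0.56 at percentile 0.19, with 4 of 19 at least 2-fold lower. Nfkb2 and Tnip1 in this list were lower by -1.53 and -1.44, but by -0.48 and -0.56 after the correction, which also moved the list to -0.23 at percentile 4.28. Immediate early genes had a median of -0.33 at percentile 1.74, and -0.14 at percentile 4.91 after the correction. Junb was 2.30-fold lower while Fosb was 1.95-fold higher, and their log2 differences of -1.20 and 0.86 became -0.70 and 1.55 after the correction.

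Interferon-induced genes followed the same direction. Of 20 type I interferon response genes 19 were below 0 and 6 at least 2-fold lower, with a median of -0.62 at percentile 0.08. Zbp1, a sensor of Z-form nucleic acids, was 2.37-fold lower (2.17 to 2.60), and Oas3, an antiviral synthetase, 2.34-fold lower, whereas Mx2 and Ifi44 had log2 differences of 0.00 and 0.09. After the correction Oas3 was at -0.65, short of 2-fold. Interferon-gamma response genes had a median of -0.36 at percentile 3.0, inside the range of random lists, and -0.41 at percentile 0.11 after the correction. Socs1, a feedback inhibitor of cytokine signalling, and Tap1, a peptide transporter of antigen presentation, were lower by -1.19 and -1.14, or by -0.31 and -0.44 after the correction. Irf1 was 1.22-fold higher (1.17 to 1.27).

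The inflammasome and pyroptosis list had a median of -0.30 at percentile 13.2, and of -0.57 at percentile 0.01 after the correction. Nlrp3, an inflammasome sensor, was 2.08-fold lower (1.85 to 2.35), Casp1 1.27-fold (1.02 to 1.60) and the pore-forming protein gene Gsdmd 1.47-fold (1.32 to 1.65). In the same list Txnip, which encodes a thioredoxin-binding protein, was 2.05-fold higher and the kinase gene Nek7 1.37-fold higher (1.22 to 1.54). On the size rule, Mefv and Nlrp6 passed 2-fold, at -1.12 and -1.40, the second only without the correction, where it was at -0.90. Genes of cell death machinery did not stand apart, with a median of -0.14 at percentile 27.8. Within this list Mcl1, an anti-apoptotic factor, was 2.79-fold lower (2.65 to 2.93) and the necroptosis kinase gene Ripk3 2.57-fold lower (2.06 to 3.23). In the other direction, 9 of 26 measured members were above 0, and the caspase gene Casp6 was 1.63-fold higher (1.32 to 2.02). Casp8 differed by 0.07, with an interval of the ratio from 0.931 to 1.19. Targets of p53 had a median of -0.19 at percentile 22.3, with the pro-apoptotic gene Bbc3 5.28-fold lower (3.93 to 7.20), Trp53inp1 1.53-fold higher (1.42 to 1.64) and Ccng1 1.42-fold higher (1.21 to 1.68).

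**Figure D3:**
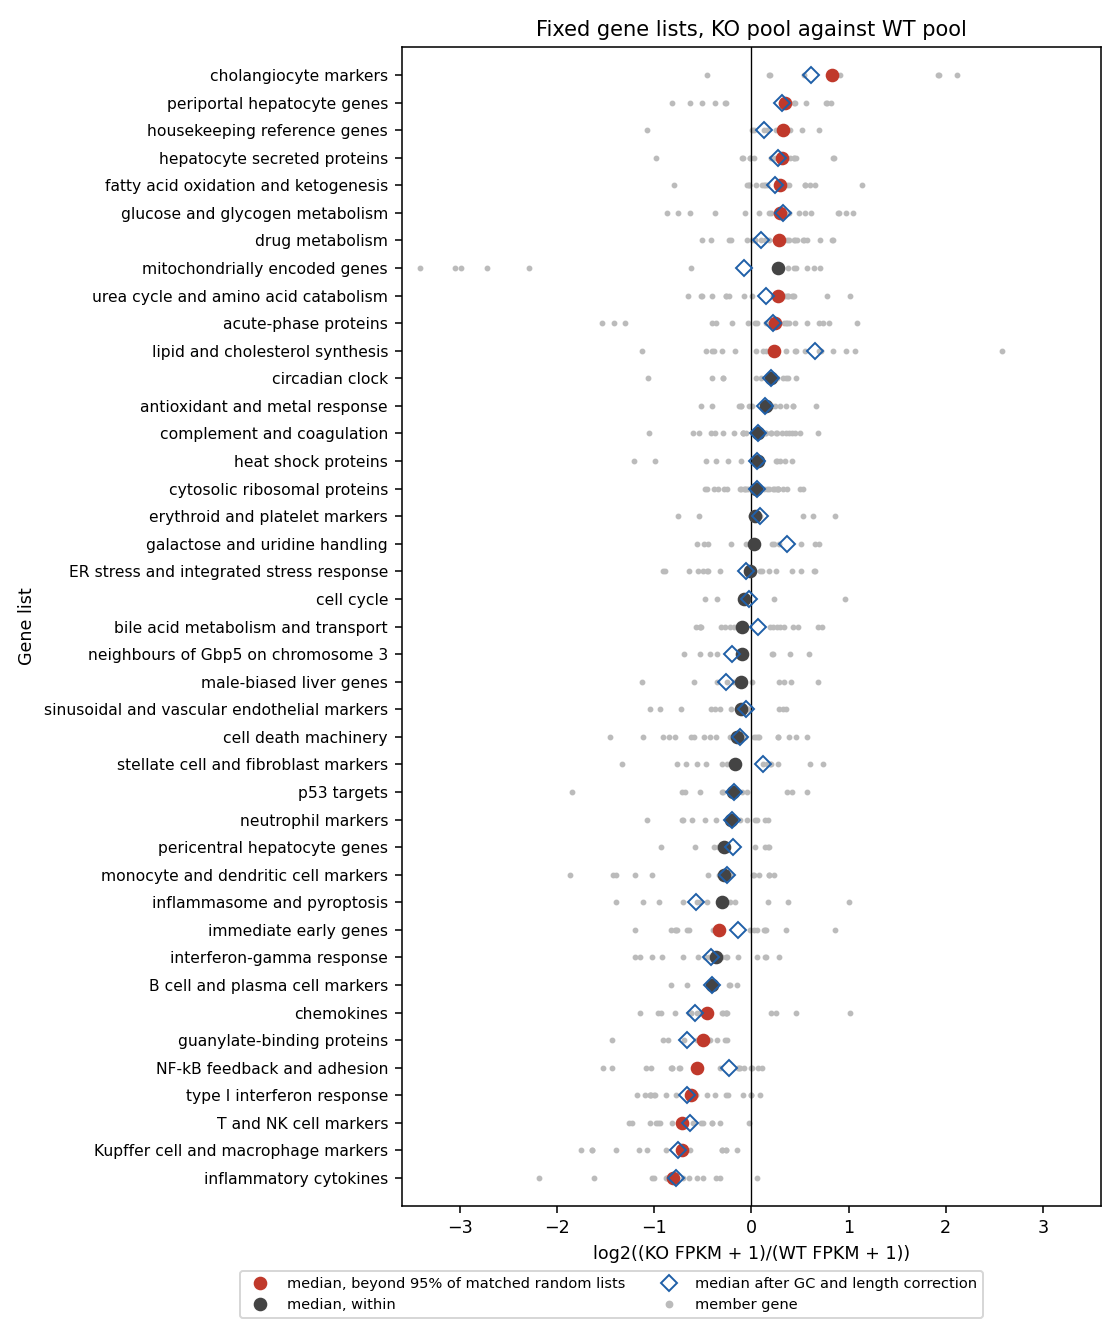
Log2 difference between the KO and WT pools (FPKM with a pseudocount of 1) for 41 gene lists fixed before the data were examined, with grey points for member genes, filled circles for medians (red beyond 95% of 10000 matched random lists) and open diamonds for medians after the GC and length correction. Inflammatory cytokines lie lowest, at -0.81, and cholangiocyte markers highest, at 0.83 before the correction.

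Markers of resident macrophages were lower as well. All 15 Kupffer cell and macrophage genes were below 0, with a median of -0.71 at percentile 0.01. Marco, a scavenger receptor, was 3.41-fold lower (3.22 to 3.62), the complement gene C1qa 3.15-fold (2.92 to 3.40) and Clec4f, a lectin specific to Kupffer cells, 2.26-fold (2.12 to 2.40), while Lyz2 was 1.11-fold lower. All 14 T and NK cell genes were below 0, with a median of -0.71 at percentile 0.01. The cytotoxic granule gene Gzmb was 2.45-fold lower (2.15 to 2.79), and Trbc1, with 51 and 10 reads, 4.04-fold lower (2.03 to 8.93). In the monocyte and dendritic cell list the antigen presentation genes H2-Ab1 and H2-Eb1 were 3.70-fold and 2.72-fold lower, whereas Plac8 was 1.17-fold higher. That list as a whole had a median of -0.28 at percentile 4.77, and of -0.25 at percentile 1.66 after the correction. Neutrophil markers had a median of -0.21 at percentile 20.7. S100a8 had 142 FPKM in WT and 149 in KO, and Csf3r, the receptor for the Csf3 product, was 2.19-fold lower, or at -0.59 after the correction. B cell and plasma cell genes had a median of -0.41 at percentile 10.3. Markers of endothelium had a median of -0.11 at percentile 41.5, those of stellate cells and fibroblasts -0.17 at percentile 27.9, and those of erythroid cells and platelets 0.03 at percentile 53.8. Stab1 among the endothelial markers was 2.13-fold lower, but at -0.06 after the correction.

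Hepatocyte gene groups lay on the other side, by smaller amounts. Before the correction housekeeping reference genes lay as high, with a median of 0.32 at percentile 99.4. A rise of this size was thus not particular to hepatocyte genes, although after the correction the housekeeping list was inside the range of random lists. Hepatocyte secreted proteins had a median of 0.31 at percentile 99.7 with none of 20 genes at 2-fold. Alb was 1.80-fold higher (interval 1.80 to 1.81) and Apob 1.79-fold higher, whereas Apoe was 1.98-fold lower, with a log2 difference of -0.98 that became -0.48 after the correction. Acute-phase proteins had a median of 0.24 at percentile 98.3. Hamp, which encodes the iron hormone hepcidin, was 2.13-fold higher and Saa1 1.75-fold higher (1.69 to 1.81), the latter at 1.14 after the correction. In the same list Socs3 was 2.93-fold lower and Cebpd 2.72-fold lower, at -0.63 and -1.07 after the correction. Fatty acid oxidation and ketogenesis genes had a median of 0.30 at percentile 99.9, with Cyp4a14 2.25-fold higher (0.95 after the correction) and Acot1 1.83-fold lower. Glucose and glycogen genes had a median of 0.29 at percentile 99.4, with G6pc 2.11-fold higher (0.96 after the correction). Lipid and cholesterol synthesis genes had a median of 0.23 at percentile 99.6, and of 0.66 after the correction. Besides Pnpla3, Me1 was 2.14-fold higher and the transcription factor gene Mlxipl 2.21-fold lower, or at 0.88 and -0.41 after the correction. Periportal hepatocyte genes had a median of 0.34 at percentile 99.8 with members on both sides, such as Hal, 1.80-fold higher, and Pigr, 1.76-fold lower. Pericentral genes had a median of -0.28 at percentile 6.82. Cyp2e1 differed by 0.04.

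Several groups changed place among random lists with the correction. Drug metabolism genes went from 0.28 at percentile 99.8 to 0.10 at percentile 69.7, with Cyp3a11 1.79-fold higher (1.77 to 1.82). Urea cycle and amino acid genes went from 0.27 at percentile 99.4 to 0.15 at percentile 83.7, with Cps1 1.71-fold higher and Bhmt 1.57-fold lower. Housekeeping reference genes went from 0.32 at percentile 99.4 to 0.135 at percentile 81.8. Before the correction 12 of 13 were above 0, whereas Gapdh was 2.32-fold lower (2.05 to 2.63), at -0.97 after the correction. Galactose and uridine genes, relevant to the handling of D-galactosamine, lay at 0.02 and at 0.37 at percentile 99.9 after the correction. Bile acid genes lay at -0.10 at percentile 21.03, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 1.53-fold lower (1.34 to 1.74). Complement and coagulation, ribosomal protein, heat shock, antioxidant, ER stress, cell cycle, circadian clock and Gbp5 neighbour lists had medians from -0.10 to 0.20, all inside the range of random lists. The neighbour list also held Lrrc8d of chromosome 5, so its median does not describe the flanks of Gbp5 alone. On chromosome 3, Gbp2, Gbp3 and Gbp7 were at -0.43, -0.69 and -0.35, and Gtf2b at 0.59.

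Cholangiocyte markers had the highest median before the correction, 0.83, above all 10000 random lists. After the correction they lay at 0.61, under lipid and cholesterol synthesis genes at 0.66. Of 9 measured, 8 were above 0, and 3 were at least 2-fold higher, namely Krt19, Muc1 and Cd24a. Epcam was 2.17-fold higher (1.75 to 2.69) on 138 and 237 reads. Markers shared by the small bile ducts did not move in the same way. Sox9 was 1.41-fold lower (1.27 to 1.56), and Krt7, with 127 and 129 reads, had a ratio of 1.28 with an interval from 0.995 to 1.65.

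Of the 41 lists with 5 or more measured members, 8 lay below and 10 above 95% of random lists, against 2.05 if lists fell at random. After the correction, 10 lay below and 8 above, and 6 and 7 did so both ways. Lists share genes and are not independent of each other. Male-biased genes had a median of -0.10 at percentile 13.7, and of -0.26 at percentile 0.885 after the correction. Of 15 female-biased genes, Cyp4a14 and Cyp17a1 were measured at 1 FPKM or more. Among sex chromosome genes, Ddx3y had 854 reads in WT and 873 in KO, and Xist had 0 and 4. In the mesothelial, adipose, muscle and pancreas list, 3 genes were measured, of which Msln and Upk3b were 2.45-fold and 2.58-fold lower and Cidec was at 0.19.

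Mitochondrially encoded transcripts took 5.91% of reads in WT and 7.12% in KO. Of 13 protein genes, 5 were lower in KO by -2.29 to -3.42, namely mt-Co2, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l. They lie between positions 7013 and 10173 of the mitochondrial genome. Of the other 8, mt-Atp8 was at -0.63, and 7 were above 0, up to 0.70 for mt-Nd1, although mt-Co1 went from 0.27 to -0.07 with the GC and length correction. The 5 genes are covered over at least 95% of their length by annotated parts of a nuclear copy on chromosome 1 (24611535 to 24616197, minus strand). Identity was 99.7% to 100%, so the values of the 5 genes are uncertain. Stretches of the copy without annotation were not counted. Reads assigned to the annotated parts of the copy were themselves lower in KO, at 67.5% to 84.7% of WT.

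**Figure D4:**
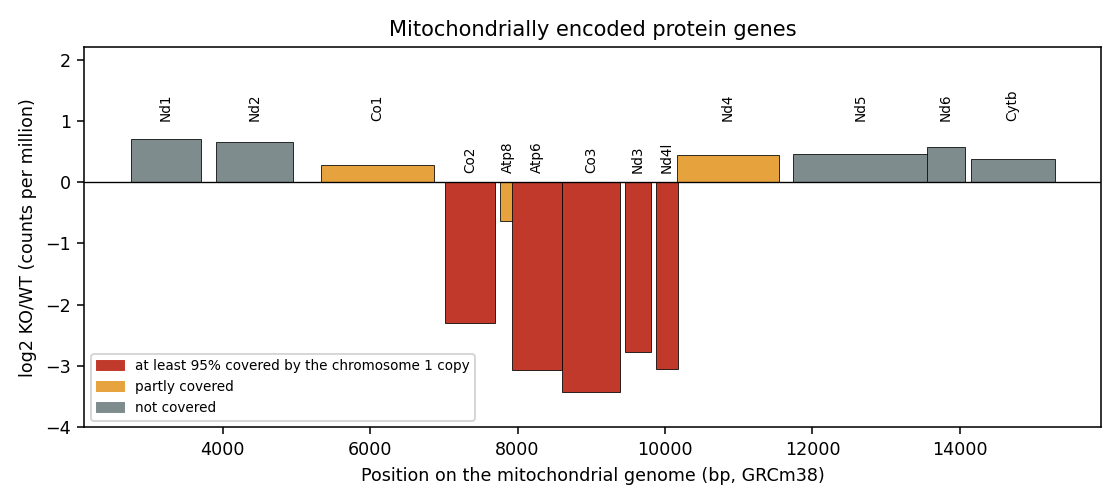
Log2 difference between the KO and WT pools (CPM) for the 13 mitochondrial protein genes, drawn at their positions in bp, with 1 library per group. Genes at least 95% covered by annotated parts of the chromosome 1 copy (red) lie between -2.29 and -3.42, and partly covered (orange) and uncovered (grey) genes between -0.63 and 0.70.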

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

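The 209 labels without an annotated gene lie outside all comparisons of the report, and 197 of them had 10 reads or more. Of these, 23 were at least 2-fold higher in KO than in the WT control library and 42 at least 2-fold lower, with a median log2 difference of -0.26. They were singled out because they hold signal in data that no comparison used. No explanation was tested.

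In the weighing below, the GC and length correction itself, the tests on genes of low and high GC content, on other non-hepatocyte cells, on pancreatic enzymes, on abundant intestinal transcripts and on the mitochondrial copy were chosen only after the results were seen. With 1 pool per genotype, genotype, differences between the 4 animals of each pool and library preparation are confounded in every pattern, and genotype as a cause was not tested.

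More genes were lower than higher in KO, and inflammatory, interferon and macrophage genes were lower as groups. For the excess of lower genes, how much comes from a technical trend with GC content and length stays open: the lower share went from 73.1% to 54.9% after the correction, which centres genes of like GC content on 0, and a share of 38.8% at or below the median GC content against 85.2% above it restates the trend. Among protein-coding genes 65.7% of calls (exact interval 60.5% to 70.5%) stayed lower after the correction, from 88.5% before. The interval takes genes as independent, which they are not, so it is too narrow. In the part at or below that median, 63 were lower and 41 higher, or 60.6% lower, against 93.2% above it. For protein-coding genes these values argue only weakly against the trend as the whole cause. For the lists, the trend is argued against as the whole cause, because the median of the 87 pooled members went only from -0.63 to -0.56 (SE 0.054), below all 10000 random lists. A lower share of all non-hepatocyte cells is argued against too, because macrophage markers lay -0.85 (sum of SEs 0.21) from endothelial and stellate markers after the correction. This leaves fewer macrophages, weaker macrophage responses and the genotype open. The lower values were not particular to macrophages. All 14 T and NK cell genes were below 0 after the correction too, with a median of -0.63 at percentile 0. Neutrophil and B cell genes lay at -0.20 and -0.40, at percentiles 8.1 and 3.4, inside the range of random lists. A lower share of immune cells of several kinds was not tested and stays open.

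From the genes highest in KO, 9 were picked after their values were seen, most of them known from mucosal or ductal epithelium and 1 of them the chymotrypsinogen gene Ctrb1. Their median log2 difference in CPM of 4.47 is therefore set by selection and is no evidence of a theme. It was 4.44 after the correction. The medians by GC content ran only from 0.28 to -0.88, so the correction could not have removed a difference of that size. The outcome of this test was fixed beforehand, and nothing is drawn from it. Pancreatic tissue is argued against by 13 abundant digestive enzyme genes, whose reads came to 0.673% of those of Ctrb1. For intestinal epithelium, the test fixed first came out in its favour. The median log2 difference in CPM was 1.003 over 4 genes with 10 reads or more. It was 0.55 on FPKM with the pseudocount, short of the limit of 1. Of the 4 genes 2, Vil1 and Olfm4, were over 2-fold higher. In a second test chosen afterwards, 5 abundant intestinal transcripts (Alpi, Lct, Sis, Muc2 and Defa24) had 3 reads in KO. That was 0.0403% of the reads of the 9 genes. These 5 came from the same list of 12 once the first result was known. Other members had more reads, such as Olfm4 with 39 in WT and 101 in KO, and Fabp2 with 897 and 881. The second test therefore cannot decide, and intestinal epithelium stays open. More bile duct or gallbladder epithelium in the KO pool is a candidate explanation. The 15 simple epithelium genes, listed after the pattern was noticed but before their own values were looked at, had a median log2 difference in CPM of 0.98 before and 1.28 after the correction with 14 above 0, against a limit of 0.5, and of 0.44 and 0.53 on FPKM with the pseudocount, which shrinks low genes. Such genes are not particular to bile duct or gallbladder. The test therefore goes with more epithelium of some kind and cannot tell its source. Small bile duct genes had a corrected median in CPM of 0.25 over 5 genes, and whether such tissue came from dissection or from the liver itself stays open.

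The 5 mitochondrial genes lower in KO by more than 2-fold are those almost wholly covered by annotated parts of the nuclear copy on chromosome 1. The lowest of the 8 genes not wholly covered by those parts was at -0.63. That gene, mt-Atp8, lies between mt-Co2 and mt-Atp6, where the copy has a stretch without annotation. It may thus lie inside the copy too, so coverage as counted cannot decide whether every covered gene is lower. Handling of reads that match both places remains a candidate explanation, and why it would differ between the 2 libraries was not tested.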

How the results depend on the processing

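The GC and length correction, CPM, TMM scaling, protein-coding genes only and totals without mitochondrial genes were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Among the lists that stood apart and the named genes that passed 2-fold, none changed sign under the 12 alternatives; the other called genes were not followed one by one. Some lists inside the range of random lists did change sign, such as the mitochondrial one, at 0.27 and at -0.07 after the correction. Gbp5 stayed at least 2-fold lower in all of them, from -1.38 to -1.55, the latter with an equal FPKM sum. With a pseudocount of 0.1, 507 genes were higher and 1391 lower; with an equal FPKM sum 712 and 1431; 77 were higher at 5 FPKM or more and 85 among protein-coding genes; 368 were lower after the correction and 1186 on CPM. More low genes pass with a smaller pseudocount, and fewer genes are compared at 5 FPKM or more and among protein-coding genes; the cause was not tested otherwise. Without a filter the calls are the same by construction.

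The guanylate-binding protein median left its place beyond random lists with a pseudocount of 0.1 (-0.59), median ratio scaling (-0.45), no filter (-0.44), 5 FPKM (-0.43), protein-coding genes only (-0.44) and totals without mitochondrial genes (-0.49). Without a filter, interferon-gamma (-0.36), inflammasome (-0.30), B cell (-0.35), mesothelial and other tissue (-0.088) and mitochondrial genes (0.27) gained a place. At 5 FPKM, inflammasome (-0.54) and monocyte genes (-0.67) gained one, and T and NK cell genes (-1.04) had too few members for a percentile. The correction gave a place to interferon-gamma (-0.41), inflammasome (-0.57), galactose (0.37), monocyte (-0.25) and male-biased genes (-0.26), and took it from NF-kB (-0.23), drug (0.10), urea cycle (0.15), immediate early (-0.14) and housekeeping genes (0.135). CPM gave interferon-gamma genes (-0.42) a place. The cause of these moves was not tested. Ratios resting on fewer than 10 reads in a library, such as those of Ctrb1, Spink4, Moxd1 and Ccl20, are limited by depth, and the single library per group limits every comparison.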

Other observations

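Epithelial genes beyond the fixed lists were examined in both libraries after the data were seen. Rab25, a vesicle-trafficking GTPase of epithelial cells, had 18 reads in WT and 53 in KO, 3.71-fold higher (2.14 to 6.74), and the epithelial transcription factor gene Klf5 had 13 and 46, 4.46-fold higher (2.37 to 9.00). Tmprss2, a membrane serine protease gene, was 3.24-fold higher (2.54 to 4.18) and Prom1 2.85-fold higher (2.05 to 4.00). Pkhd1, which encodes fibrocystin of bile duct cilia, was 1.73-fold higher (1.41 to 2.11). Spint2, which hepatocytes may also express, had a ratio of 1.03 (0.975 to 1.09). The 15 genes of this set with 10 reads or more had a median log2 difference in CPM of 0.98, and of 1.28 after the correction. Of stomach genes, Atp4a had 32 and 35 reads, and Muc5ac had 0 and 3.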
